A study of Mus musculus with 15 samples.

How the data were processed

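RNA from mouse hearts was measured on 15 one-colour Affymetrix-type arrays, in which biotin-labelled material from 1 heart sample binds short probes grouped into probe sets. Per the labels, total RNA was extracted with Trizol and column purification. The deposited values are intensities on a linear scale, 1 per probe set and array. The software, background correction and scaling by which the authors made them are not given in the sources used here. The lowest value was 0.95 on every array, and 81 to 191 of the 12422 probe sets of an array lay at that floor. Array medians ran from 173.7 to 216.8 and array means from 414.4 to 464.6, and how the authors scaled the arrays stays unknown.

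The labels place each array in 1 of 4 groups, control or cardiac knockout at 2 or 4 weeks of age, with 3, 4, 3 and 5 arrays (control and knockout at 2 weeks, then at 4 weeks). Nothing in the labels states that arrays of a group came from separate mice. If they did not, the p-values measure only a spread between arrays that could be technical. No array repeated another: at most 0.0322% of the probe sets had equal values above the floor in any 2 arrays.

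The rule fixed beforehand kept the deposited scaling if all medians lay within a set ratio. The observed ratio of the highest to the lowest median was 1.248, just inside that limit, so no further normalization was applied, and quantile normalization and median scaling were run as alternatives. Values were used as log2(intensity + 16). A fold change is therefore on that scale, which understates changes of dim genes. The platform annotation gave 1 gene symbol to 10833 probe sets, several to 396 and none to 1193. Symbols were updated through gene IDs in a table of the GRCm38.p6 assembly, in which 10817 of the single-symbol probe sets had an entry. No coordinates were used, because the build behind the array annotation is not given in the sources used here. Each of 8251 genes was represented by its single-symbol probe set with the highest mean. The lowest 40% of genes were left out as dim, which left 4950 genes tested. The dimmest tested gene had a mean intensity of about 183.9 when transformed back from log2. For arrays, precision is limited by their number.

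Tests used limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 15 arrays, a shared spread with an intensity trend, two-sided moderated tests and Benjamini-Hochberg adjustment over the 4950 genes. Genes with an adjusted p under 0.05 are called. Errors beside log2 differences are standard errors of the fit. The 5 comparisons were knockout against control at 4 weeks and at 2 weeks, the difference between these effects, and 4 against 2 weeks within control and within knockout hearts. Adjusted p-values printed in the text come from limma. For genes left out as dim, they come from the fit to all 8251 genes. For the 2 Mnat1 probe sets, they come from the fit to all 12422 probe sets.

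A total of 24 gene lists with 535 genes was fixed before the data were examined. Of these genes 443 had a single-symbol probe set and 346 were tested, and 14 symbols were matched through synonyms. Lists were tested with limma's camera, which sets a list against all other tested genes, with a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 24 lists. Named genes followed a rule fixed before the data were examined. For the knockout comparisons it took a set of transcription, energy and stress genes whatever their values, the 8 largest rises and falls among called genes whose groups did not overlap, and the 3 members of each list with the smallest p. For the other comparisons it took the 6 largest rises and falls and the same list members, of which the text names some. One of the 8 falls at 4 weeks is a probe set listed under a microRNA symbol and has no value here, since the probe was not matched to the microRNA itself. Grcc10 was named after its values were seen.

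The arrays fell into 2 sets of 6 and 9 by their correlation over all probe sets, a split the labels do not mention. The lowest correlation of 2 arrays within a set was 0.937 and the highest between sets was 0.924. Each set held arrays of all 4 groups. Set 1 held 1 control and 2 knockout arrays at each age, and set 2 held the rest. The sets also differed in array median, with a mean of 210.6 in set 1 and 181.6 in set 2 and no overlap. The sets were found from the values and are called array sets. After this was seen, every comparison was run again with the array set as a block, within each set, and with the set and quantile normalization together. The sex of each mouse, which the labels do not give, was inferred from Xist against Uty. By this inference 4 of the 5 knockout and 1 of the 3 control arrays at 4 weeks came from females, and 1 of 4 and 1 of 3 at 2 weeks. A further fit had both array set and inferred sex as blocks.

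The fits were tested on simulated data for the 4950 genes, built from each gene's mean level, spread and array-set shift with no group effect, with 200 genes changed in each of 5 simulations. For knockout against control at 4 weeks, the fit without a block recovered 14.2% of 1.5-fold and 48.8% of 2-fold changes, and the fit with the array set as a block recovered 71.6% and 93.2%. For the comparison at 2 weeks the shares were 12.8% and 49.8% without the block and 70.4% and 93.0% with it. False calls made up 0.316% to 5.40% of the simulated calls. Other alternatives tried were offsets of 1 and 64, other filters on dim genes, all probe sets in place of genes, no intensity trend, array weights, only the arrays compared, the sample number as a replicate block, each array left out in turn and other thresholds.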

Results

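The series asked how loss of MAT1 from heart muscle cells changes gene expression. MAT1, encoded by Mnat1, is the assembly factor of the kinase complex that also holds Cdk7 and cyclin H. This complex is part of the general transcription factor TFIIH and acts on RNA polymerase II. Knockout hearts carried 2 floxed Mnat1 alleles and a Cre recombinase driven by the alpha-myosin heavy chain promoter. Control littermates carried the same Cre and kept 1 wild-type allele. Hearts were sampled at 2 and 4 weeks of age, with 3 control and 4 knockout arrays at 2 weeks and 3 control and 5 knockout arrays at 4 weeks. Intensities were analysed as deposited. Because the arrays split into 2 array sets that cross the groups, values with the array set as a block and within each set are given beside the counts.

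Mnat1 was read by 2 probe sets, both dim. The intensity of the brighter probe set was 145.3 ± 85.9 (SD, n = 3) in control and 210.5 ± 88.6 (SD, n = 5) in knockout hearts at 4 weeks. At 2 weeks it was 154.2 ± 88.7 (SD, n = 3) and 182.4 ± 107 (SD, n = 4). Per array, this probe set read 243.8, 106.3 and 86.0 in control and 300.3, 314.3, 147.6, 140.7 and 149.4 in knockout hearts at 4 weeks. At 2 weeks it read 87.9, 119.8 and 255.0 in control and 73.1, 110.8, 296.3 and 249.3 in knockout hearts. The dimmer probe set read 74.3, 40.1 and 79.2 in control and 74.3, 67.6, 51.6, 78.3 and 38.9 in knockout hearts at 4 weeks. At 2 weeks it read 43.0, 41.4 and 86.3 in control and 32.5, 23.7, 52.03 and 33.9 in knockout hearts. The knockout minus control difference at 4 weeks was 0.53 ± 0.47 (log2) for the brighter and -0.03 ± 0.27 for the dimmer probe set, neither past the threshold. At 2 weeks it was 0.16 ± 0.49 for the brighter and -0.47 ± 0.28 for the dimmer probe set (adjusted p = 1 for both), and with the array set as a block -0.04 ± 0.15 (adjusted p = 0.998) and -0.55 ± 0.22 (adjusted p = 0.912). At 4 weeks, blocking on the array set, the brighter one was higher in knockout hearts by 0.45 ± 0.15 (adjusted p = 0.0384 over all probe sets). Where these probes lie relative to the floxed segment is not given in the sources used here, and cells other than muscle cells keep the gene. The Mnat1 probe sets therefore do not check the labels, and knockout below means hearts so labelled.

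At 4 weeks, genes of the extracellular matrix were higher and genes of mitochondrial fuel use lower in knockout than in control hearts. The rises taken by the naming rule were led by Mfap4, a microfibril protein, at 4.03 ± 0.65 (log2), and Lox, which cross-links collagen and elastin, at 3.73 ± 0.54. Next came the growth factor Tgfb2 at 3.27 ± 0.32 (9.65-fold), Postn, a matrix protein of activated fibroblasts, at 3.03 ± 0.54, and the cell cycle inhibitor Cdkn1a at 3.02 ± 0.30. Col8a1 rose by 2.86 ± 0.43, the myosin light chain Myl1 by 2.85 ± 0.56 and Eln, which encodes elastin, by 2.83 ± 0.37. The falls were led by the transcription elongation factor gene Tcea3 (-2.71 ± 0.35), the interferon-induced GTPase gene Iigp1 (-2.66 ± 0.47) and the glutathione transferase gene Gsta4 (-2.62 ± 0.39). Mid1ip1, linked to lipid synthesis (-2.43 ± 0.23), Mlf1 (-2.14 ± 0.30), Sema5b (-2.05 ± 0.42) and the carbonic anhydrase gene Car14 (-2.01 ± 0.30) also fell. Adjusted p-values of these 15 genes lay at or below that of Sema5b, 0.00529. The rule took only genes whose groups did not overlap, so their equal sign in both array sets follows from the choice. Sizes differed between the sets. Within set 1 and set 2, Mfap4 differed by 2.06 and 5.09 and Lox by 2.22 and 4.61. Eln differed by 1.74 and 3.40, and Iigp1 by -0.62 and -3.78. In all, 554 of 4950 genes were called, 326 higher and 228 lower. In 859 genes (17.4%) every knockout array lay on 1 side of every control array, where chance gives 3.57%.

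The matrix list showed the broadest rise. Of 29 tested members 27 rose and none fell, over all genes and adjusted over the list alone, with a median 2.38-fold higher (camera adjusted p = 2.24e-27, and adjusted p = 0.0133 with an estimated correlation). Col4a1, a basement membrane collagen, rose by 1.16 ± 0.08 and Bgn, a small proteoglycan, by 1.70 ± 0.17. When the array set was a block 28 rose, and the camera adjusted p was 0.0508 with an estimated correlation. The matrix median was 1.14 (log2) within set 1 and 1.56 within set 2. Endothelial markers did not move with it: of 13 tested 1 rose, Eng (0.54 ± 0.14), and the list median was 0.06, which turned to -0.04 after quantile normalization. No macrophage (10 tested) or lymphocyte (6 tested) marker was called, nor any adjusted over the list alone. The array-set block called 3 endothelial markers higher and 1 lower, and 1 lymphocyte marker higher. Of 9 smooth muscle and pericyte markers 2 rose, also adjusted over the list alone: Acta2, which the stress list holds too, by 1.01 ± 0.19, and Cnn1 by 1.45 ± 0.33. Camera called none of these 4 lists (adjusted p = 0.288 to 0.936). The smooth muscle median was 0.29, and it was -0.07 within set 1, where Cnn1 differed by 0.43 against 2.03 within set 2.

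Genes of mitochondrial energy supply fell. Of 25 tested genes for fatty acid uptake and oxidation 16 fell and none rose (21 adjusted over the list alone), with a median of -0.71 (camera adjusted p = 8.97e-20, and adjusted p = 0.00847 with an estimated correlation). Acaa2, the last enzyme of the beta-oxidation spiral (-1.02 ± 0.11), Cpt2, which reforms acyl-CoA inside mitochondria (-1.16 ± 0.13), and the acylcarnitine carrier Slc25a20 (-0.87 ± 0.11) were among them. Of 17 pyruvate dehydrogenase and citric acid cycle genes 6 fell (12 adjusted over the list alone; camera adjusted p = 3.04e-10, and adjusted p = 0.00847 with an estimated correlation), among them Idh2 (-1.05 ± 0.10), Cs, which encodes citrate synthase (-0.56 ± 0.10), and Ogdh (-0.69 ± 0.14). Of 13 genes for ATP transfer and mitochondrial carriers 6 fell (7 fell and 1 rose adjusted over the list alone; camera adjusted p = 5.31e-07, and adjusted p = 0.0107 with an estimated correlation). Those that fell included the myoglobin gene Mb (-0.52 ± 0.05), the adenine nucleotide carrier Slc25a4 (-0.49 ± 0.05) and Ak1 (-0.69 ± 0.11). Of 58 oxidative phosphorylation genes 16 fell (27 fell and 1 rose adjusted over the list alone), with a median of -0.30 and camera adjusted p = 2.02e-16. The oxidative phosphorylation call was lost with an estimated correlation (adjusted p = 0.064). Ndufb2 of complex I (-0.49 ± 0.07), Cox7a1 of complex IV (-0.62 ± 0.09) and Atp5a1 of ATP synthase (-0.41 ± 0.07) fell. With the array set as a block the falls numbered 23 of 25, 13 of 17, 9 of 13 and 44 of 58 in these 4 lists. The block also ended the camera call with an estimated correlation for citric acid cycle and carrier genes (adjusted p = 0.0861 for both). Of 18 glycolysis genes 2 rose and 3 fell (4 and 5 adjusted over the list alone): Pfkp rose by 1.79 ± 0.25, while Pfkm, the muscle isoform of the same enzyme (-0.87 ± 0.17), and Ldhb (-0.52 ± 0.10) fell. Camera did not call the glycolysis list (adjusted p = 0.229).

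The regulators of these pathways did not pass the test. Ppargc1a, the PGC-1alpha coactivator, was dim and differed by -0.43 ± 0.27 (adjusted p = 0.474), Esrra by -0.25 ± 0.12 (adjusted p = 0.254) and Ppara by -0.37 ± 0.15 (adjusted p = 0.141). None of 16 tested regulators was called, over all genes or adjusted over the list alone. Under the array-set block 6 fell, among them Ppara (-0.38 ± 0.13, adjusted p = 0.0279) and Mef2d (-0.63 ± 0.10, adjusted p = 0.00018), and Ppara was -0.06 within set 1 and -0.55 within set 2. Among 8 tested TFIIH and polymerase kinase genes Gtf2h1 rose by 0.72 ± 0.14 and Cdk8 by 0.54 ± 0.16, the same 2 as adjusted over the list alone. Cdk7 was dim and differed by 0.26 ± 0.21. Cyclin H and Ppargc1b had no single-symbol probe set here.

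Of 16 stress and fetal program genes 8 rose and none fell (9 adjusted over the list alone; camera adjusted p = 7.91e-05, and adjusted p = 0.204 with an estimated correlation). The natriuretic peptide genes Nppa and Nppb rose by 2.00 ± 0.33 (4.01-fold) and 0.78 ± 0.19. Rcan1, a target and inhibitor of calcineurin, rose by 1.84 ± 0.20, Timp1 by 1.76 ± 0.28 and the skeletal actin gene Acta1 by 0.65 ± 0.11. Of 13 sarcomere genes 4 fell and 1 rose, the same numbers as adjusted over the list alone (camera adjusted p = 0.00477, and adjusted p = 0.121 with an estimated correlation). Myh6 (-0.39 ± 0.07), the troponin I gene Tnni3 (-0.75 ± 0.06) and Myom2 (-1.77 ± 0.23) fell, while Myh7 differed by -0.11 ± 0.07 (adjusted p = 0.454). Of 15 calcium handling and ion channel genes 5 fell and 2 rose (6 and 2 adjusted over the list alone; camera adjusted p = 4.27e-05, and adjusted p = 0.00847 with an estimated correlation). Hrc, a calcium-binding protein of the sarcoplasmic reticulum (-1.57 ± 0.12), the gap junction gene Gja1 (-1.36 ± 0.09) and the calcium release channel gene Ryr2 (-1.19 ± 0.17) fell.

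Smaller groups of stress genes moved in both directions. Of 10 p53 targets and apoptosis genes 3 rose, Cdkn1a, Phlda3 (1.39 ± 0.15) and Mdm2 (0.58 ± 0.18), and adjusted over the list alone 3 rose and 1 fell. Of 19 integrated stress and unfolded protein response genes 2 rose and 2 fell, as adjusted over the list alone, including Atf3 (1.80 ± 0.28), the mitochondrial chaperone gene Hspd1 (-0.71 ± 0.12) and Herpud1 (-1.16 ± 0.22). Of 20 antioxidant genes 2 rose and 3 fell (4 and 4 adjusted over the list alone), including Gpx3 (1.57 ± 0.13) and the mitochondrial thioredoxin reductase gene Txnrd2 (-0.63 ± 0.14). Of 14 cell cycle genes 1 rose, Tk1 (0.53 ± 0.16), and none did adjusted over the list alone. Of 5 atrial and conduction markers Nppa rose while Stard10 (-0.89 ± 0.15) and the connexin gene Gja5 (-0.67 ± 0.19) fell, as adjusted over the list alone; Nppa and Gja5 are also on the stress and calcium lists. Of 5 skeletal muscle markers Myl1 rose, and 2 rose adjusted over the list alone. No erythroid (4 tested), adipocyte (5 tested) or lung (3 tested) marker was called, though 1 erythroid and 1 adipocyte marker rose adjusted over the list alone. With the array set as a block 4 p53 genes rose and 1 fell, 2 integrated stress genes rose and 6 fell, and 6 antioxidant genes rose and 5 fell. The block also called 4 cell cycle, 3 skeletal muscle and 2 adipocyte genes higher, and 1 erythroid marker higher and 1 lower. The erythroid median was 0.47 within set 1 and -0.39 within set 2. The camera test called no list named from the p53 targets onward. Its direction was down for antioxidant and atrial genes, whose medians were 0.08 and 0.20. The p53 median of 0.06 was -0.05 after quantile normalization.

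Blocking on the array set called 1756 genes at 4 weeks, 1150 higher and 606 lower, including all 554 above, and within set 1 and set 2 the counts were 1169 and 1435. Quantile normalization without the block turned the split to 241 higher and 308 lower, and median scaling to 172 and 210. The block together with quantile normalization called 880 higher and 858 lower. The share of higher calls was then 50.6%, against 65.5% with the block alone, so most of the excess of higher calls was lost under that scaling. Knockout arrays at 4 weeks came mostly from females by inferred sex and control arrays mostly from males. Array set and inferred sex as blocks together called 1564 genes, including all 554. Without control 4 wk replicate 2 the count was 307, and without control 4 wk replicate 3 it was 353. Of the 58 called genes named here, 8 lost the call without 1 or another array: Nppb, Cdk8, Mdm2, Txnrd2, Tk1, Eng, Cnn1 and Gja5. Of 111 called genes with several tested probe sets, 14 had a probe set of the opposite sign.

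**Figure D1:**
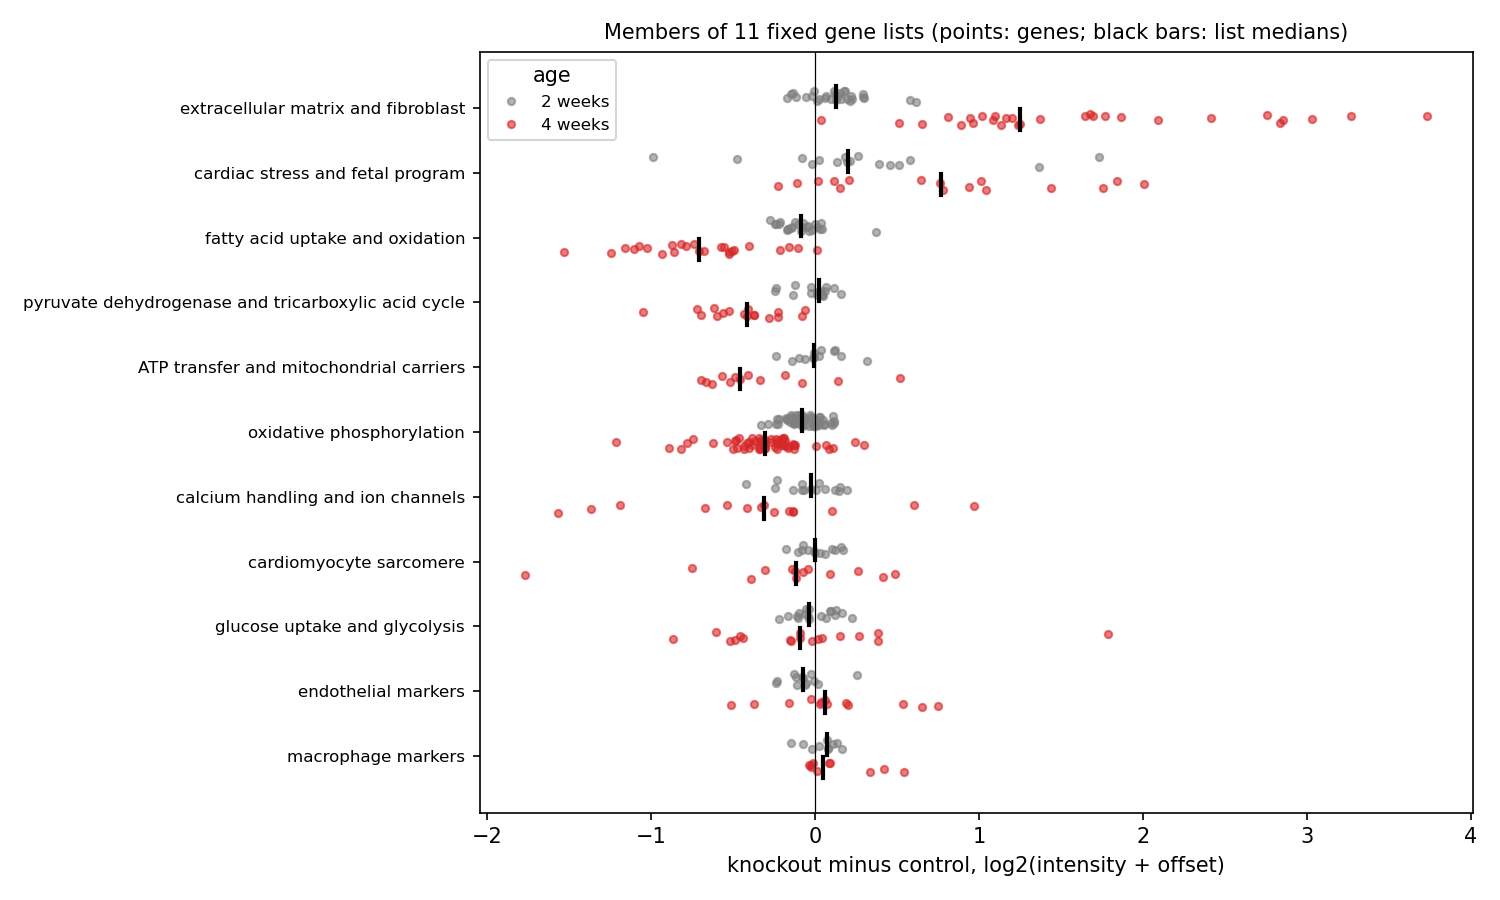
Each point is a gene of 1 of 11 fixed lists, placed by its knockout minus control difference in log2(intensity + 16) at 2 weeks (grey) and 4 weeks (red), and black bars are list medians. At 4 weeks 27 of 29 matrix genes rose and 16 of 25 fatty acid genes fell; at 2 weeks no member of either list was called.

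At 2 weeks 1 gene was called. The skeletal actin gene Acta1, part of the fetal heart program, was 2.57-fold higher in knockout hearts (1.36 ± 0.12 log2, adjusted p = 5.74e-05). Its intensity was 2721 ± 236 (SD, n = 3) in control and 7037 ± 712 (SD, n = 4) in knockout hearts. Nppa differed by 1.73 ± 0.35 (adjusted p = 0.317), with 786.2 ± 305 (SD, n = 3) against 2744 ± 1320 (SD, n = 4). With the array set as a block 4 genes were called: Acta1, Nppa (1.85 ± 0.19, adjusted p = 0.00011) and the stress gene Ankrd1 (0.47 ± 0.08, adjusted p = 0.0208) rose, and Grcc10, chosen after its values were seen, fell by 0.50 ± 0.07 (adjusted p = 0.00379). Within set 2, 3 genes were called, and within set 1, 1 gene. Cdkn1a differed by 1.29 ± 0.32 and Gtf2h1 by 0.61 ± 0.15 (adjusted p = 1 for both).

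The energy genes gave no call at 2 weeks. Ppargc1a, dim here too, differed by 0.45 ± 0.28, Esrra by 0.06 ± 0.13 and Ppara by -0.07 ± 0.16 (adjusted p = 1 for each). Nppb differed by 0.19 ± 0.20, Myh6 by -0.08 ± 0.07, Myh7 by -0.02 ± 0.08 and Cdk7 by 0.05 ± 0.22. Of the 16 stress and fetal program genes 1 rose, 4 adjusted over the list alone, and camera gave adjusted p = 4.27e-07 (adjusted p = 0.227 with an estimated correlation). Camera also placed fatty acid genes (median -0.09, adjusted p = 9.87e-05) and oxidative phosphorylation genes (median -0.08, adjusted p = 2.07e-06) lower, and matrix genes (median 0.13, adjusted p = 0.00113) higher, with no member called. All 3 calls were lost with an estimated correlation (adjusted p = 0.263, 0.369 and 0.605). Further camera calls at 2 weeks, for the TFIIH (adjusted p = 0.00192), calcium handling (adjusted p = 0.0453) and p53 (adjusted p = 0.0414) lists, were lost likewise (adjusted p = 0.0895, 0.227 and 0.263). At an unadjusted p under 0.05 limma gave 51 genes, and 271 with the array set as a block, where chance alone gives 247.5, and 120 genes (2.42%) had groups without overlap where chance gives 5.71%.

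**Figure D2:**
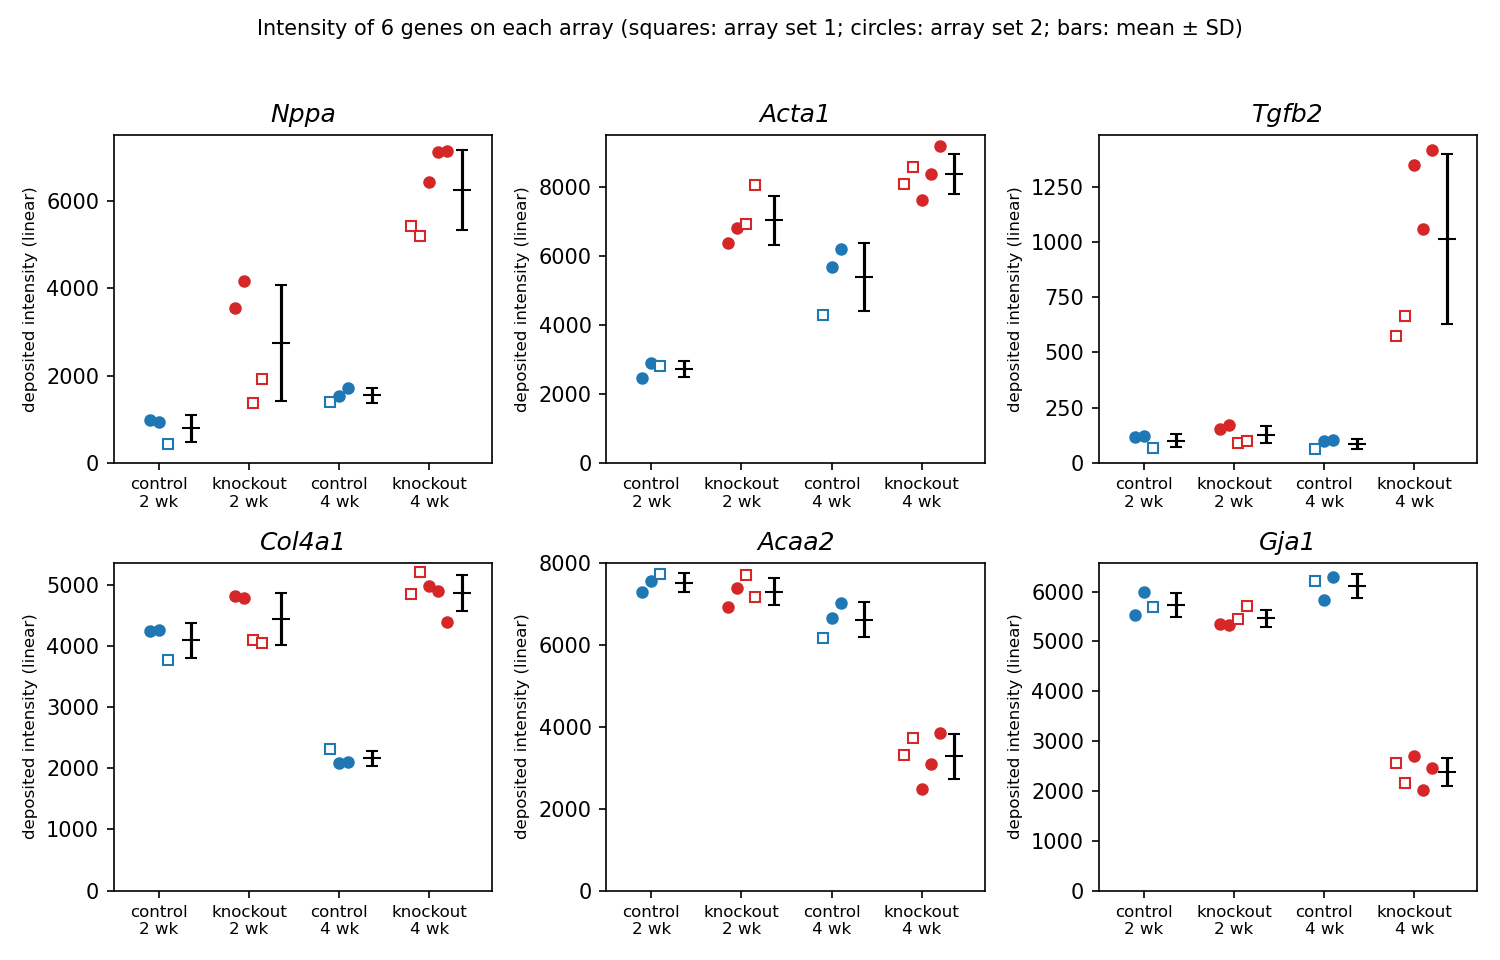
Deposited linear intensity of 6 genes on each array (squares, array set 1; circles, array set 2), with mean ± SD bars, for control (blue) and knockout (red) hearts. Acta1 in knockout hearts at 2 weeks read 6375 to 8046 against 2455 to 2904 in control hearts, and Gja1 at 4 weeks read 2018 to 2704 against 5830 to 6294.

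The knockout effects at both ages were then compared. Across the 4950 genes they correlated with Pearson's r = 0.404 and Spearman's rho = 0.381, where genes are not independent replicates and the 2 ages share no arrays. The jackknife standard error of r over arrays was 0.366, so r lay little more than 1 standard error above 0. It was 0.223 without control 2 wk replicate 3, 0.246 without CKO 2 wk replicate 1, 0.253 without CKO 2 wk replicate 2 and 0.264 without control 4 wk replicate 3. Array weights gave 0.18. Blocking on the array set gave r = 0.464 and rho = 0.442, and r was 0.207 within set 1 and 0.427 within set 2. Of the 554 genes called at 4 weeks 459 (82.9%) had the same sign at 2 weeks, against 65.5% of all genes. Their median difference was 0.78 in size at 4 weeks and 0.13 in the same direction at 2 weeks. Of the higher calls 1 gene, Acta1, was called at both ages, where independent lists would share 0.0659.

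The effect itself differed with age for 77 genes, with 38 more positive and 39 more negative at 4 weeks. The most positive differences were those of Lox (3.85 ± 0.78), Tgfb2 (2.98 ± 0.47), Eln (2.98 ± 0.53), Col5a2 (2.60 ± 0.58), Mfap5 (2.28 ± 0.35) and Tgfb3 (2.19 ± 0.42). Of the 29 matrix genes 12 were called, 26 adjusted over the list alone, all more positive at 4 weeks (camera adjusted p = 1.25e-33, and adjusted p = 0.00642 with an estimated correlation). The most negative were Mid1ip1 (-2.23 ± 0.33), Tcea3 (-2.21 ± 0.51), Plbd1 (-2.01 ± 0.25), Car14 (-1.94 ± 0.43), Thrsp, a regulator of lipid synthesis (-1.93 ± 0.40), and Ptgds, a prostaglandin D synthase gene (-1.91 ± 0.30). Of the 25 fatty acid genes 5 were more negative (12 adjusted over the list alone; camera adjusted p = 8.2e-19, and adjusted p = 0.00569 with an estimated correlation). The difference for Acta1 was -0.72 ± 0.16 (adjusted p = 0.0386), a smaller effect at 4 weeks. Control arrays read 2455 to 2904 for Acta1 at 2 weeks and 4292 to 6187 at 4 weeks. Knockout arrays read 6375 to 8046 and 7631 to 9176, so the smaller effect went with a rise in control hearts and not with a fall in knockout hearts. For Nppa the difference was 0.27, not past the threshold.

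The difference between ages was called for 616 genes with the array set as a block, including all 77, and for 297 within set 1 and 358 within set 2. Median scaling left 9 genes, 1 more positive and 8 more negative. Leaving out control 4 wk replicate 2 or replicate 3 left 20 or 25 genes, control 2 wk replicate 1 or replicate 2 left 25 or 38, CKO 4 wk replicate 3 left 49, and CKO 2 wk replicate 3 or replicate 4 left 47 or 45. Of 34 called genes examined by name 14 were called whichever array was left out, and those that were not included Lox, Eln, Col5a2, Tgfb3, Tcea3, Car14, Thrsp and Acta1.

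**Figure D3:**
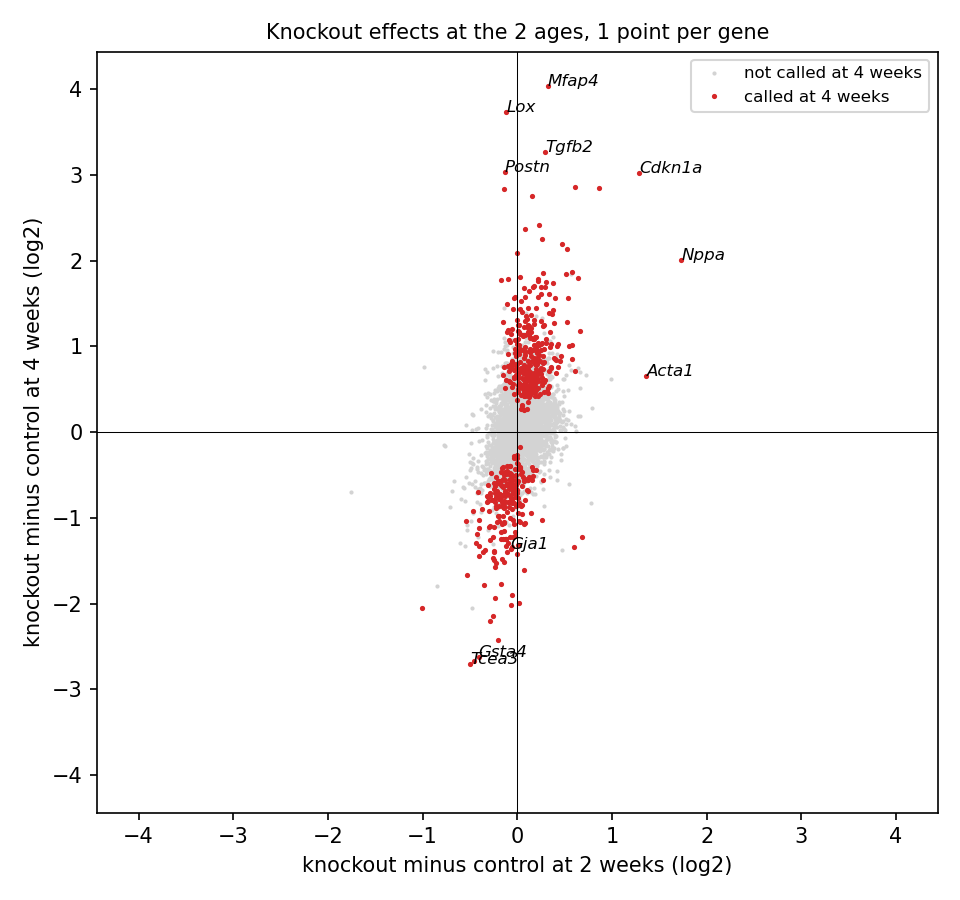
Knockout minus control difference in log2(intensity + 16) of each of 4950 genes at 2 weeks (horizontal) and at 4 weeks (vertical), with genes called at 4 weeks in red. The 554 red points spread along the vertical axis, and the difference between ages was itself called for 77 genes.

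In control hearts, 36 genes changed from 2 to 4 weeks, 24 higher and 12 lower. The largest rises were Cd74 (2.82 ± 0.36) and H2-Aa (1.75 ± 0.32), of antigen presentation, Ptgds (2.73 ± 0.23), Thrsp (2.00 ± 0.31), and the detoxification genes Nqo1 (1.63 ± 0.23) and Gstm2 (1.49 ± 0.22). The largest falls were Eln (-2.33 ± 0.41), Itm2a (-1.92 ± 0.35), Col6a3 (-1.44 ± 0.30), the growth factor Igf2 (-1.40 ± 0.25), Col1a1 (-1.23 ± 0.24) and Marcks (-1.20 ± 0.25). Of 29 matrix genes 5 fell and none rose (18 adjusted over the list alone), among them Col4a1 (-0.92 ± 0.09) and Lum (-0.68 ± 0.12). Endothelial markers had a median of -0.31 with none called (camera adjusted p = 0.00757, and adjusted p = 0.366 with an estimated correlation). The matrix list had a median of -0.75 and camera adjusted p = 2.08e-21, lost with an estimated correlation (adjusted p = 0.0733). Lpl rose by 0.64 ± 0.10, Idh2 by 0.60 ± 0.11, Acta1 by 0.97 ± 0.12, Ankrd1 by 0.60 ± 0.10 and the lipid desaturase gene Scd1 by 1.13 ± 0.23. Groups without overlap were found for 10.1% of genes, where chance gives 10%. The array-set block called 293 genes, 142 higher and 151 lower, including all 36, with 266 within set 2. Set 1 held 1 control array at each age, so the comparison within it rests on single arrays. Median scaling called 10 higher and 1 lower, and no gene was called from the 6 control arrays alone. Without control 4 wk replicate 2 or replicate 3, 8 or 7 genes were called, and without control 2 wk replicate 1 or replicate 2, 8 each. Within set 1 the arrays at 4 weeks were all female and those at 2 weeks all male by inferred sex, and Eln differed by -0.84 there and by -3.07 within set 2. Of the 19 genes named here 6 were called whichever array was left out: Cd74, Ptgds, Nqo1, Gstm2, Acta1 and Col4a1.

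In knockout hearts, 325 genes changed from 2 to 4 weeks, 186 higher and 139 lower. The largest rises were Tgfb2 (2.80 ± 0.30), Col8a1 (2.74 ± 0.39), the epoxide hydrolase gene Ephx1 (2.37 ± 0.61), the uridine kinase gene Uck2 (2.13 ± 0.31), Myl1 (2.02 ± 0.52) and Tgfb3 (2.00 ± 0.27). The largest falls were the potassium channel subunit gene Kcne1 (-2.63 ± 0.53), Mlf1 (-2.35 ± 0.27), Gsta4 (-1.86 ± 0.36), the slow skeletal troponin T gene Tnnt1 (-1.83 ± 0.31), Tcea3 (-1.75 ± 0.32) and Car14 (-1.74 ± 0.27). Of 25 fatty acid genes 16 fell and none rose (19 adjusted over the list alone; camera adjusted p = 1.6e-20, and adjusted p = 0.0145 with an estimated correlation), including Acaa2 (-1.16 ± 0.10), Cpt2 (-1.09 ± 0.12) and Slc25a20 (-0.86 ± 0.10). Of 17 citric acid cycle genes 3 fell (7 adjusted over the list alone; camera adjusted p = 0.016 with an estimated correlation), among them Cs (-0.66 ± 0.10). Of 13 carrier genes 5 fell, as adjusted over the list alone, with the same camera adjusted p, among them Mb (-0.48 ± 0.05). Of 15 calcium handling genes 4 fell and 1 rose, as adjusted over the list alone (camera adjusted p = 0.0164 with an estimated correlation), including falls of Gja1 (-1.20 ± 0.08) and Hrc (-0.97 ± 0.11). Of 58 oxidative phosphorylation genes 10 fell (13 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.185 with an estimated correlation). Blocking on the array set ended the camera call with an estimated correlation for the citric acid cycle, carrier and calcium lists (adjusted p = 0.108 for each) and not for fatty acid genes (adjusted p = 0.018). Tnni3 also fell (-0.52 ± 0.06). Of 29 matrix genes 7 rose and none fell (13 adjusted over the list alone), including Bgn (1.43 ± 0.15), and camera gave adjusted p = 5.68e-11 (adjusted p = 0.136 with an estimated correlation). Of 16 stress and fetal program genes 7 rose (10 rose and 2 fell adjusted over the list alone; camera adjusted p = 4.6e-06, and adjusted p = 0.139 with an estimated correlation), including Fhl1 (1.71 ± 0.32), Rcan1 (1.20 ± 0.18) and Nppa (1.31 ± 0.30). Nppa is also on the atrial list, of whose 5 tested markers 2 rose (median 0.65, camera adjusted p = 0.195). Gpx3 (1.76 ± 0.12) and Nqo1 (1.70 ± 0.18) also rose, as did Scd1 (1.51 ± 0.19) and Car3 (1.76 ± 0.47) of 5 adipocyte markers and Lyz2 (1.18 ± 0.30) of 10 macrophage markers. The array-set block called 1242 genes, 709 higher and 533 lower, including all 325, with 1052 within set 1 and 905 within set 2. Quantile normalization turned the split to 173 higher and 186 lower, and to 643 and 656 together with the block, so the excess of higher calls was not kept under that scaling. Median scaling called 193 genes. By inferred sex, knockout arrays came mostly from females at 4 weeks and mostly from males at 2 weeks. Within set 1 they were all female at 4 weeks and all male at 2 weeks, so age and sex cannot be told apart there. Array set and inferred sex as blocks together called 1117 genes, 602 higher and 515 lower, including all 325. The count was 207 without CKO 4 wk replicate 3, 212 without CKO 2 wk replicate 3, 211 without CKO 2 wk replicate 4 and 197 from the 9 knockout arrays alone. Ephx1, Myl1, Car3, Lyz2 and Nppa lost the call without 1 or another array, and Kcne1 differed by -1.14 within set 1 and -4.01 within set 2.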

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

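The tests on list scores and on inferred sex, and all fits with the array set, were chosen after the results they bear on were seen; the counts over other splits of the arrays and the test of brightness were fixed before theirs.

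Among 93 named genes, an array stood far from the others of its group in 7 of 186 groups of values tested. Chance gives about 1 in 20, or 9.30. Distance was judged on the log2 scale used for the tests, by the gap of the extreme array as a share of the group's range. The intensities in brackets are linear, and shares taken from them would differ. In knockout hearts at 4 weeks the gap of the extreme array took 0.723 of the group's range for Esrra (CKO 4 wk 3, 665.9 against 816.3 to 882.5), 0.719 for Sema5b (CKO 4 wk 5, 24.6 against 104.2 to 167.9), 0.826 for Gpx3 (CKO 4 wk 4, 7378 against 5465 to 5758), 0.846 for Gja5 (CKO 4 wk 3, 194.9 against 299.1 to 323.1) and 0.741 for Plbd1 (CKO 4 wk 3, 106.0 against 141.2 to 155.8). In knockout hearts at 2 weeks it took 0.90 for Ndufb2 (CKO 2 wk 1, 4194 against 4418 to 4443) and 0.854 for H2-Aa (CKO 2 wk 4, 151.9 against 128.6 to 131.8).

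Of 64 genes named for a knockout effect and tested, 28 had an effect that differed between 2 and 4 weeks by the limma test of the difference itself. Over all genes, 77 of 4950 did. Many of the 64 were named for the size or p of the same knockout effects, so a higher share among them follows in part from the choice. Values are the effect at 4 weeks less that at 2 weeks (log2). The effect was more positive at 4 weeks for Lox (3.85), Tgfb2 (2.98), Eln (2.98), Pfkp (1.89), Bgn (1.41), Gpx3 (1.36), Rcan1 (1.33), Phlda3 (1.05) and Col4a1 (1.05). It was more negative for Mid1ip1 (-2.23), Tcea3 (-2.21), Car14 (-1.94), Mlf1 (-1.89), Myom2 (-1.59), Hrc (-1.34), Gja1 (-1.29), Idh2 (-1.07), Cpt2 (-1.02), Acaa2 (-0.98), Ak1 (-0.81), Slc25a20 (-0.78), Acta1 (-0.72), Ldhb (-0.68), Tnni3 (-0.68), Mb (-0.64), Slc25a4 (-0.52), Atp5a1 (-0.44) and Ndufb2 (-0.43). Acta1 was the member of this group whose effect was larger at 2 than at 4 weeks while positive at both ages.

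A rise of matrix genes with a fall of oxidative genes at 4 weeks may come from a changed make-up of the tissue. A lower share of muscle cells would raise the markers of all other cells alike, but the mean of matrix genes less that of endothelial markers rose by 1.51 (log2) from control to knockout hearts (exact permutation p = 0.0179, two-sided, the smallest that 56 splits can give). It would also lower muscle genes alike, but the mean of fatty acid genes less that of sarcomere genes differed by -0.51 (exact permutation p = 0.0179). This argues against such a loss as the whole pattern, though the sarcomere mean itself differed by -0.19 (exact permutation p = 0.0179). Sarcomere genes were also brighter, with a mean log2 value of 12.39 against 10.88 for fatty acid genes in control hearts at 4 weeks. Whether bright probe sets respond as fully was not tested. Unequal sex was argued against by a matrix median of 1.21 with array set and inferred sex as blocks, against 1.28 with the set alone. Within set 1, where all 4-week arrays were female by inferred sex, the median was 1.14, though with 1 control array. Within set 2 it was 1.56. There the 4-week controls were male and 2 of 3 knockout arrays female, so that value cannot speak to sex. A small loss of muscle cell RNA as part of the pattern, more fibroblasts, more matrix expression per fibroblast and an effect of the knockout inside muscle cells stay open, each as a hypothesis, since the pattern was found and tested on the same data.

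The split of the arrays into 2 sets may be technical. Inferred sex differed by only 5.56 percentage points between the sets (50.0% and 44.4% female), which argues against sex. A shift by brightness was seen in all 4 groups in the same direction, but with rho between -0.196 and -0.224 across genes it lay between the bounds set beforehand; the smallest size, 0.196, leaves this open. The sets did not overlap in array median (199.6 to 216.8 in set 1, 173.7 to 190.9 in set 2) or in probe sets at the floor (81 to 111 and 122 to 191), while array means overlapped (414.4 to 448.4 and 424.4 to 464.6); whether this comes from processing or from the samples was not tested. Apart from sex, no biological explanation was tested, since both sets hold all groups.

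Other splits of the same arrays were counted for each comparison. No correction was made over the comparisons. At 4 weeks 2 of 56 splits, the real one included, called at least 554 genes. This share, 3.57%, lay under the level set, but a split that followed the array sets called 1765. Since such a split can call more genes than the real one, the share does not by itself exclude chance. With the array set as a block 1 of 56, the real split, called at least 1756 genes (639 the highest other). At 2 weeks 3 of 35 splits called at least 1 gene and the highest, again along the array sets, called 2060; with the block 2 of 35 called at least 4 and the highest, along the array sets too, called 32. Chance cannot be excluded for the counts at 2 weeks. For the difference between ages 3 of 100 drawn splits of 1960 called at least 77 (highest other 293), and with the block 3 of 100 called at least 616 (highest other 1315). Both shares of the drawn splits lay under the level set. These splits exchanged knockout and control arrays within each age, which removes the knockout effect itself. They therefore cannot decide whether that effect differs with age. The share over all 1960 has a 95% interval of 0.357% to 6.99% in both fits, so an exclusion of chance over all splits is not shown. In knockout hearts between ages 4 of 100 drawn splits of 126 called at least 325, the highest, along the array sets, with 2744, and the interval for all 126, 3.17% to 6.35%, again leaves this open beyond the drawn splits. With the block 1 of 100, the real split, called at least 1242 (778 the highest other). The interval for all 126, 0.794% to 2.38%, lay under the level set there. Without the block, the highest counts at 4 weeks, at 2 weeks and in knockout hearts between ages came from splits along the array sets. For the difference between ages, the drawn split most along the array sets, judged by 4-week arrays, called 0 genes in both fits. What raised the highest counts for that difference was not tested. In control hearts 10 splits are too few for a share under 0.05: 1 split, the real one, called 36 genes and the highest other called 0, and with the block 1 called 293 and the highest other 0.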

How the results depend on the processing

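Fits with the array set, within a set or with inferred sex were chosen after seeing the data. Arrays were not treated as paired by number, since of 19 same-numbered pairs only 7 had deviations correlated over 0.1 (range -0.819 to 0.889), against 43 of 43 pairs within an array set and 0 of 40 between sets. With the array set removed 12 of the 19 passed, against 17 of 64 pairs with different numbers, so some relation by number stays open. With the sample number as a replicate block 316 genes were called at 4 weeks (554 without it), 23 for the difference between ages (77), of which 5 were more positive and 18 more negative at 4 weeks (38 and 39 without it), 15 with age in control (36), 13 higher and 2 lower (24 and 12), and 151 in knockout hearts (325). At 2 weeks the block left the count at 1. No background values were used here, so how far dim genes lie above background stays unknown.

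Counts moved by over 1.5 times as follows, in the order 4 weeks, difference between ages, control age and knockout age where given. Array weights, whose estimate stopped before its tolerance was reached, gave 1133, 637, 353 and 987 (2 at 2 weeks). Median scaling gave 9, 11 and 193 for the last 3. Only the arrays compared gave 0 and 197 for age in control (tests of 6 arrays) and knockout. An adjusted p under 0.01 gave 285, 18, 8 and 135, and under 0.10 gave 121 for the difference and 66 for control age. Array set as a block gave 1756, 616, 293 and 1242 (4 at 2 weeks), with quantile normalization 1738, 647, 296 and 1299 (4), and with inferred sex 1564, 450, 322 and 1117 (4). Within set 1 the counts were 1169, 297 and 1052 (control age 51 moved by less), within set 2 1435, 358, 266 and 905 (3 at 2 weeks), where a lone control array in set 1 is assumed to vary like the other groups. Quantile normalization alone gave 2 at 2 weeks. The cause was not tested, except that stricter or looser thresholds and fewer arrays change counts by construction.

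Leaving out each array in turn gave 307 to 590 at 4 weeks, 1 to 2 at 2 weeks, 20 to 83 for the difference, 7 to 46 for control age, 207 to 335 for knockout age, and r from 0.223 to 0.534 between the effects at both ages. The jackknife standard error of r, 0.366, is nearly as large as r itself (0.404), so that no alternative moved r by more than it says little about stability.

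For named genes, 2687 of 3127 planned values kept direction and side of the threshold, 427 lost the call, 5 gained it and 8 changed sign. Of 780 added values 737 stayed, 21 lost it, 19 gained it and 3 changed sign. Of 58 genes called at 4 weeks 50 were called without each array in turn, and the others were Nppb, Cdk8, Mdm2, Txnrd2, Tk1, Eng, Cnn1 and Gja5. None of the sign changes was in a called effect. At 2 weeks Esrra was -0.019 within set 2, Ppara 0.11 within set 1, Nppb -0.11 with array weights, and Myh7 0.0074 with the replicate block and 0.053 within set 2. Without 1 array, at 2 weeks Esrra ran from -0.013 to 0.10, Ppara from -0.14 to 0.017, Nppb from -0.022 to 0.30 and Myh7 from -0.065 to 0.0085, and the difference between ages for Nppa from -0.016 to 0.64. The cause was not tested. Counts of list members stayed within 1.5 times in 2016 of 2376 planned and 320 of 600 added values.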

Other observations

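Both tests of a hypothesis below bear on a pattern first seen in these data; the test on knockout hearts was chosen after its values were seen.

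From 2 to 4 weeks 5 of 29 matrix genes fell in control hearts and 7 of 29 rose in knockout hearts. Neither list call held with an estimated correlation (limma camera adjusted p = 0.0733 and 0.136), while that for the difference between ages in the knockout effect did (adjusted p = 0.00642). The mean log2 value of the 29 matrix genes was 9.98 ± 0.25 (SD, n = 3) in control hearts at 2 weeks, 9.23 ± 0.13 (SD, n = 3) at 4 weeks, 10.11 ± 0.36 (SD, n = 4) in knockout hearts at 2 weeks and 10.85 ± 0.19 (SD, n = 5) at 4 weeks. The difference in control hearts, -0.76, had an exact permutation p of 0.1, the smallest that 20 splits can give. Elastin (Eln) read 1921 ± 605 (SD, n = 3) and 401.6 ± 257 (SD, n = 3) in control and 1815 ± 804 (SD, n = 4) and 2658 ± 398 (SD, n = 5) in knockout hearts at 2 and 4 weeks.

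A candidate explanation is that knockout hearts at 4 weeks merely keep the level of 2 weeks. Against this for the list as a whole, the matrix mean was higher by 0.74 at 4 than at 2 weeks in knockout hearts (exact permutation p = 0.00794, two-sided, 126 splits). The list median was lower, 0.40, with 0.57 within set 1 and 0.27 within set 2. Of 29 members 27 lay higher and 7 were called higher. For single members the explanation stays open. Col4a1 in knockout hearts read 4049 to 4815 at 2 weeks and 4385 to 5200 at 4 weeks. In control hearts Col4a1 read 3764 to 4264 and 2077 to 2305. The permutation left out array set and inferred sex, and knockout arrays were mostly female at 4 weeks and mostly male at 2 weeks. A wider likeness to 2-week hearts may still exist. Over 4921 genes outside the matrix list, the knockout effect at 4 weeks and the difference of 2-week from 4-week control hearts correlated with r = 0.396, both with the array set as a block. They share the 4-week control arrays, which alone gave r = 0.558 in 100 simulations without effects. The covariance was 0.0524 against 0.0157 simulated. The excess covariance was 66.9% of the variance of the age change that was left after the variance simulated without effects was subtracted. This ratio is a slope of the knockout effect on the age change. It is not a share of variance explained. Without 1 array at a time the ratio ran from 49.7% (without control 4 wk 2) to 87.6% (without control 4 wk 1). The 3 shared controls are too few to split, genes are not independent and sex was not part of this test, so the likeness is a hypothesis, and delayed maturation cannot be separated here from a stress response that happens to move the same genes.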
